A study of Arabidopsis thaliana with 12 samples.

How the data were processed

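Total RNA of whole Arabidopsis seedlings was sequenced after ribosomal RNA depletion, from strand-specific libraries, in 12 samples that form 4 groups of 3. Groups, age, temperature and duration were taken from the titles and treatment labels, which tie each replicate number to 1 harvest date on which all groups were collected. Durations follow the group labels, 30 min for the heat treatments where the general protocol gives 2 h. No label says that the replicates came from separate cultures, so p-values measure the spread between these samples.

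The deposited values are raw counts of aligned reads per reference sequence, in the layout of a SAMtools index summary, with each mate counted on its own. Per the submitters' processing notes, Bowtie2, SAMtools and DESeq2 were used with genome build TAIR10. Versions, the role of each tool, counting parameters and a strand setting were not given in the sources used here. The reference held 87128 sequences, among them 33602 gene loci with 1 model each, of which 133 lay on the plastid and 146 on the mitochondrial genome. It also held 13230 noncoding entries, 38763 transposon or intergenic entries and 1530 microRNA precursors. Reads that match several sequences were placed by the authors' alignment, and loci that overlap another gene cannot be separated without the strand setting, so their values are uncertain. By shared 31-base words, 130 nuclear loci matched the mitochondrial genome and 2 the plastid genome over at least 50% of their words.

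Aligned reads numbered 72075150 to 152118790 per library, 82.4% to 88.7% of all reads, and nuclear loci received 37112430 to 87063684. Unplaced reads stayed out of library sizes and tests. So did ribosomal RNA, 17 loci with 0.421% to 0.934% of the aligned reads, because what remains of it measures depletion. Replicates differed by more than counting noise in every pair, with a chi-square per degree of freedom of 14.8 to 120.5.

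Tests used edgeR 4.0.16 in R 4.3.3, with TMM factors (0.648 to 1.44 over the libraries), the low-count filter filterByExpr by group at a minimum count of 10, a robust quasi-likelihood fit of all 12 libraries with the group means, and Benjamini-Hochberg adjustment at 0.05 over 26159 sequences, of which 23596 were gene loci. The biological coefficient of variation was 0.143. Standard errors of log2 fold changes are the absolute change divided by the square root of the F statistic. CPM values use the TMM factors. Comparisons were priming against control, heat shock against control and primed heat shock against heat shock, with primed heat shock against control and heat shock against priming beside them. No overlap is given between comparisons that share libraries, since these share chance values. Shares of plastid and mitochondrial counts were compared with exact two-sided permutation tests in scipy 1.17.1, and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

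Gene lists, 22 in all with 351 distinct members, were fixed from textbook knowledge before the data were examined, as were the designs, the naming rule and the alternatives, except where said below. They cover the heat and other stress responses, photosynthesis, the clock, cell division, translation, ONSEN copies and the genes of both organelles. Seed maturation and root markers stand for other material in a sample. The memory list shares members with the small heat shock protein and chaperone lists. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 66 tests (22 lists in 3 comparisons). With that correlation 17, 9 and 9 lists passed in the comparisons in the order above, and chaperones of mitochondria and plastids in priming were the only call that held with an estimated correlation. The directional test fry, which compares a list with no other genes, passed 19, 13 and 11.

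Genes are named by a rule. For each main comparison it takes up to 4 members per list with the largest change among those past the threshold, and always HSFA2, HSP101 and HSP21. Outside the lists it takes the 10 largest increases and 10 largest decreases among nuclear protein-coding genes that have a symbol, at least 20 CPM in the higher group and no overlap between the libraries of both groups. Among organellar genes it takes the 3 largest in each direction at the same level. Values are given for part of these genes, and 1 gene's result is not reported here. Symbols came from a reference annotation of assembly TAIR10.1, which held 32835 of the 33323 nuclear loci. Only 37.5% of loci had the length of a transcript there, so gene models differ and coordinates are given for HSFA2, HSP101 and HSP21 alone.

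The replicate number pairs the samples by harvest date, per the labels. Deviations from the group means of same-numbered libraries correlated by -0.07 (priming and heat shock) to 0.19 (control and priming) on average.

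Alternatives were the replicate number as a block, RLE and upper-quartile factors, no scaling factor, scaling from nuclear genes only or within an organelle, ribosomal RNA kept, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, only the compared groups in the fit, a test against a log2 change of 1 (glmTreat), and leaving out each of the 12 libraries in turn. For lists an estimated correlation and fry were added, and for shares the most abundant gene was left out. Adding nuclear loci that match the mitochondrial genome to the mitochondrial share was chosen after seeing the data, as was setting lists beside nuclear loci outside the list and the heat lists at the same level (mean CPM parted at 1, 5, 20 and 100). Counts per isoform were not compared, with 1 model per locus.

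The procedure was tested on counts simulated from these samples' means and library sizes with known changes, too few to test the scaling. Of 67, 67 and 66 sequences changed 1.5-fold, 2-fold and 4-fold it recovered 35.8%, 65.7% and 87.9% in priming against control. Heat shock against control gave 41.8%, 65.7% and 93.9%, and primed heat shock against heat shock 40.3%, 73.1% and 92.4%. False calls were 6, 12 and 12 of 25474, 25608 and 25567. Of 100 simulated lists without a change, camera gave an unadjusted p under 0.05 to 5, 2 and 2 in these comparisons. Simulated genes varied independently of each other, so these lists could not test the preset correlation for real lists.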

Results

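Whole seedlings of Arabidopsis thaliana, wild-type accession Col-0, were grown in shaken liquid culture. Total RNA libraries depleted of ribosomal RNA keep the transcripts of plastids and mitochondria beside those of the nucleus. Control seedlings were 6 days old and received no heat, and the priming group was heated to 38 °C for 30 min at the same age. At 7 days, the heat shock group was taken straight to 43 °C for 30 min. The primed heat shock group met the same 43 °C after 2 h at 38 °C and 22 h of recovery at 21 °C. These times come from the group labels, where the general protocol gives 2 h for both temperatures. Each group had n = 3 libraries, and the replicate number marks a harvest date shared by the 4 groups. Aligned reads numbered 106525697, 152118790 and 125616461 in control replicates 1 to 3, 94632872, 126358753 and 72075150 in the priming group, 111993655, 109923505 and 129161546 in the heat shock group and 89027278, 118040063 and 101931109 in the primed heat shock group.

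Expression levels are TMM-scaled CPM, given as the mean ± SD of 3 libraries, and log2 fold changes are given ± SE. A change is called where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Where leaving out 1 library, another scaling or DESeq2 moved the number of calls in a list by over 1.5-fold, the number so obtained follows in the same paragraph. The first principal component of log2 CPM held 44.4% of the variance and set the priming libraries, at 74.8 to 90.11, apart from the other groups, which lay between -37.8 and -19.3. The second, with 35.8%, placed controls at 63.9 to 67.6, heat shock at -19.6 to -13.0 and primed heat shock at -53.3 to -45.8.

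Plastid transcripts took 39.1% ± 3.25 (SD, n = 3) of the counts without ribosomal RNA in control seedlings, 44.1% ± 3.65 after priming, 54.1% ± 3.93 after heat shock and 48.9% ± 3.10 after primed heat shock. The single transcript psbA, for the D1 reaction centre protein of photosystem II, held 25.4% ± 3.33 of the counts in controls and 40.9% ± 3.43 after heat shock. The plastid share was 15.1 percentage points higher after heat shock than in controls (exact two-sided permutation test, p = 0.1), and all heat shock libraries lay above all controls. Priming against control differed by 5.06 points (p = 0.2, exact permutation test) and primed heat shock against heat shock by -5.22 points (p = 0.2, exact permutation test). With psbA left out of the counts the differences were 4.13 points for heat shock against control, 2.37 for priming against control and -2.17 for primed heat shock against heat shock. Within the harvest dates 1 to 3, the plastid share differed by 5.25, 0.287 and 9.65 points between priming and control and by -0.582, -9.54 and -5.53 points between primed heat shock and heat shock. Each of these comparisons thus had 1 direction in all 3 pairs, which an exact paired sign-flip permutation test cannot take below p = 0.25. Mitochondrial transcripts held 1.60% ± 0.0495 in controls, 1.78% ± 0.0894 after priming, 1.78% ± 0.0266 after heat shock and 1.84% ± 0.0982 after primed heat shock. The mitochondrial share was 0.179 points higher in priming and 0.177 points higher in heat shock than in control (p = 0.1 each, exact permutation test). In heat shock the difference was 0.281 points with ribosomal RNA kept and 0.134 without the most abundant mitochondrial gene. With nuclear loci that match the mitochondrial genome added, the differences were 0.331 points in priming and 0.301 in heat shock. Between primed heat shock and heat shock it differed by 0.0635 points (p = 0.4, exact permutation test), and with ribosomal RNA kept in the counts by -0.193 points and with the matching nuclear loci added by 0.167 points. With 3 libraries against 3 the smallest p the unpaired test allows is 0.1, so none of these differences could pass 0.05. Among single libraries, the mitochondrial difference between primed heat shock and heat shock was 0.0106 points without primed heat shock replicate 3 and 0.108 points without primed heat shock replicate 2, and the plastid difference between priming and control was 3.29 points without control replicate 3.

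**Figure D1:**
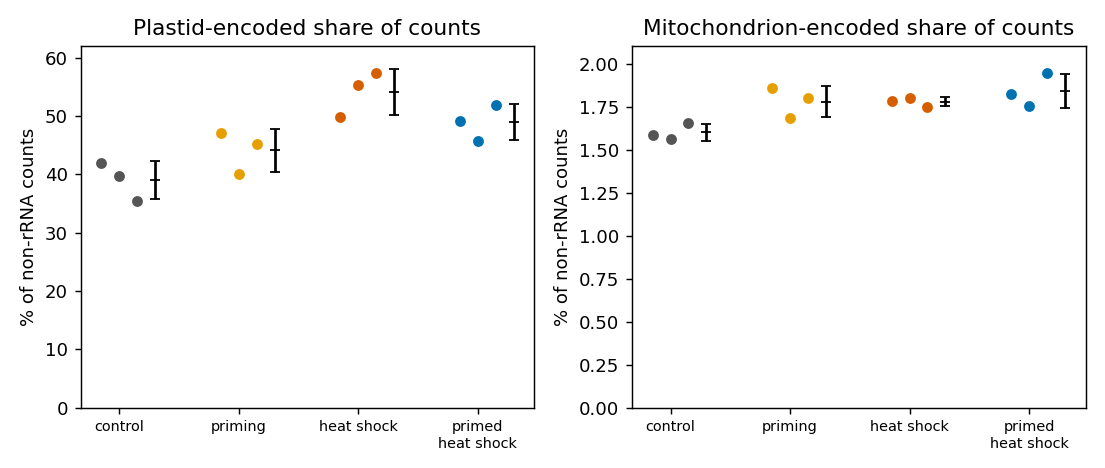
Share of counts without ribosomal RNA, in percent, from plastid-encoded genes (left) and mitochondrion-encoded genes (right) in the 4 groups. Each point is 1 library, the horizontal tick is the mean and the bar is the SD of 3 libraries. The heat shock libraries lie between 49.8% and 57.4% plastid counts and the controls between 35.5% and 41.9%.

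The comparison of priming with control asked how seedlings responded to 30 min at 38 °C. Small heat shock proteins, which hold unfolding proteins in a refoldable state, rose in 15 of 16 cases with a median log2 change of 10.02 (camera adjusted p = 7.41e-20 and adjusted p = 0.0646 with an estimated correlation). ATHSP22.0 (AT4G10250), of the endoplasmic reticulum, went from 0.919 ± 0.0775 to 1688 ± 149.8 CPM (log2 10.84 ± 0.22). HSP18.2 (AT5G59720), a cytosolic member, went from 0.493 ± 0.0968 to 741 ± 102 CPM. HSP21 (AT4G27670; chromosome 4, 13818825 to 13819971 in assembly TAIR10.1), the plastid member, rose from 0.318 ± 0.0452 to 455 ± 47.7 CPM (log2 10.49 ± 0.20, edgeR adjusted p = 7.64e-15). All 16 cytosolic and nuclear chaperones rose (median 5.43; camera adjusted p = 2.4e-19 and adjusted p = 0.0989 with an estimated correlation). HSP101 (AT1G74310; chromosome 1, 27936508 to 27940369 in TAIR10.1), the disaggregase of acquired thermotolerance, climbed from 38.2 ± 2.04 to 20982 ± 434 CPM (log2 9.10 ± 0.22, edgeR adjusted p = 3.2e-14). Hsp70b (AT1G16030) increased 1188-fold, the co-chaperone BAG6 (AT2G46240) 892-fold and the immunophilin ROF2 (AT5G48570) 293-fold. The 54 loci in the lists of small heat shock proteins, of chaperones of the cytosol, mitochondria and plastids and of memory genes together held 0.584% ± 0.0490 of the counts in control and 12.5% ± 1.12 (SD, n = 3) in priming. The list counts above were the same adjusted over the list alone. The counts were 15 rising and 1 falling small heat shock proteins (median 9.15) with no scaling factor.

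Among the 21 heat shock transcription factors 9 rose and 5 fell after priming, with a median of 0.33 (-0.52 with no scaling factor; camera adjusted p = 0.00485 and adjusted p = 0.271 with an estimated correlation). HSFA2 (AT2G26150; chromosome 2, 11135624 to 11137792 in TAIR10.1), the factor that sustains the heat response, rose from 1.41 ± 0.0766 to 1602 ± 84.3 CPM (log2 10.15 ± 0.20, edgeR adjusted p = 7.64e-15). HSFA7B (AT3G63350) rose by 9.28 ± 0.17, HSFA7A (AT3G51910) by 5.79 ± 0.16 and HSFB2B (AT4G11660), of the repressor class, by 3.71 ± 0.11 on the log2 scale. Chaperones of mitochondria and plastids rose in all 15 cases (median 2.36; camera adjusted p = 1.32e-13, and still adjusted p = 0.0414 with an estimated correlation). This was the only one of the 66 list tests to pass with an estimated correlation. The mitochondrial Hsp70 MTHSC70-2 (AT5G09590) reached 6296 ± 126 CPM from 66.3 ± 6.52 and the plastid disaggregase CLPB3 (AT5G15450) 7172 ± 125 CPM from 85.4 ± 2.80. Genes of heat stress memory, known for lasting expression after heat, rose in 11 of 12 cases (median 7.68; camera adjusted p = 8.29e-12 and adjusted p = 0.0646 with an estimated correlation). The ascorbate peroxidase APX2 (AT3G09640) among them rose by log2 8.63 ± 0.29 from 0.0940 ± 0.0685 CPM. In the unfolded protein response of the endoplasmic reticulum 11 of 17 rose and 2 fell (median 1.14; camera adjusted p = 4.23e-05 and adjusted p = 0.271 with an estimated correlation). Its Hsp70 proteins BIP1 (AT5G28540) and BIP2 (AT5G42020) rose 9.26-fold and 6.27-fold, and their partner ATERDJ3A (AT3G08970) 83.9-fold. 3 unfolded protein response genes fell when adjusted over the list alone, with the other counts the same. Falling heat shock factors numbered 3 without priming replicate 1 or 2. Calls numbered 8 rising and 10 falling heat shock factors, 12 rising and 1 falling organelle chaperones (median 1.49) and 10 rising and 1 falling memory genes (median 6.81) with no scaling factor. The numbers became 8 rising and 5 falling unfolded protein response genes (median 0.28) with no scaling factor.

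**Figure D2:**
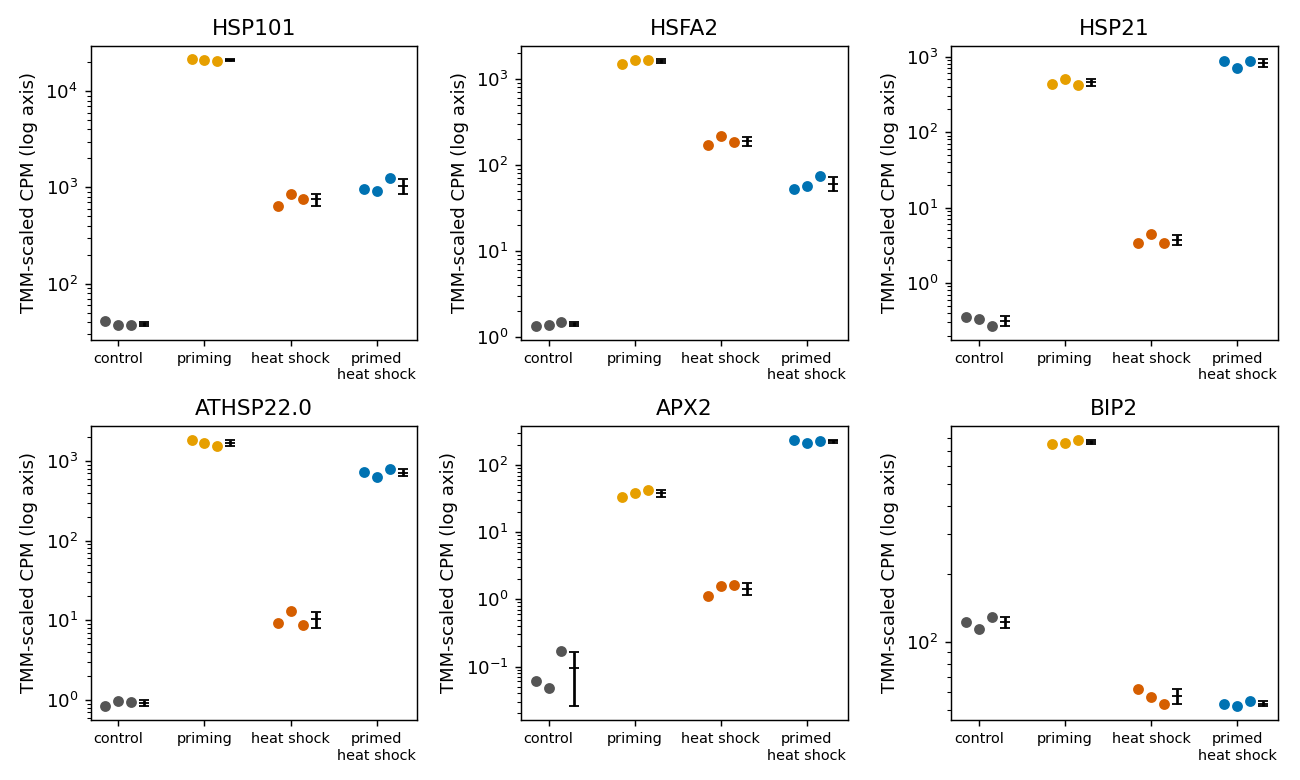
TMM-scaled CPM on log axes for HSP101, HSFA2, HSP21, ATHSP22.0, APX2 and BIP2 in the 4 groups. Points are single libraries, ticks are means and bars are SD over 3 libraries. HSP101 stands at 20982 ± 434 CPM in priming and 750.4 ± 106 CPM in heat shock, whereas HSP21 is highest in primed heat shock, at 821 ± 102 CPM.

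Genes of abscisic acid and dehydration responses rose in 11 of 15 cases after priming (median 1.204; camera adjusted p = 3.36e-05 and adjusted p = 0.416 with an estimated correlation). The galactinol synthase GOLS1 (AT2G47180) rose 119-fold and the transcription factor DREB2A (AT5G05410) 36.8-fold. In the oxidative stress list 9 of 12 rose (median 0.75, and -0.12 with no scaling factor; camera adjusted p = 1.98e-04 and adjusted p = 0.271 with an estimated correlation). The zinc-finger factor ZAT12 (AT5G59820) in it rose by log2 4.35 ± 0.28. The mitochondrial dysfunction response rose in 7 of 15 cases and fell in 1 (median 0.79, and -0.08 with no scaling factor; camera adjusted p = 0.0358 and adjusted p = 0.640 with an estimated correlation). AT2G21640 rose 2.90-fold. ONSEN retrotransposons are heat-activated elements whose copies share reads, so single loci are uncertain. Of these copies 7 of 8 rose (median 1.52; camera adjusted p = 1.07e-04 and adjusted p = 0.271 with an estimated correlation). AT1G48710 rose by log2 3.50 ± 0.19. Nuclear photosynthesis genes rose in 21 of 28 cases relative to the median locus (median 0.56, but -0.33 with no scaling factor; camera adjusted p = 1.35e-05 and adjusted p = 0.652 with an estimated correlation and adjusted p = 0.0811 with no scaling factor). PSBO2 (AT3G50820) of the oxygen-evolving complex rose by log2 1.24 ± 0.13. Cytosolic ribosomal proteins rose in 13 of 14 cases on the same scale (median 0.54, but -0.33 with no scaling factor; camera adjusted p = 5.49e-05 and adjusted p = 0.519 with an estimated correlation and adjusted p = 0.268 with no scaling factor). Among them RPS6B (AT5G10360) gave 0.71 ± 0.09 with TMM and -0.16 with no scaling factor. Nuclear loci at the CPM level of each member had a median of 0.45 for the photosynthesis list, which lay above its level by a median of 0.11, and of 0.16 for ribosomal proteins, which lay above by 0.28. 8 ONSEN copies rose and 14 ribosomal proteins rose when adjusted over the list alone, with the other counts the same. Calls came to 5 rising and 3 falling dehydration genes (median 0.34), 3 rising and 2 falling oxidative stress genes and 1 rising and 4 falling mitochondrial dysfunction genes with no scaling factor. The counts became 5 rising and 1 falling ONSEN copies (median 0.64), 1 rising and 17 falling photosynthesis genes and 0 rising and 7 falling ribosomal proteins with no scaling factor.

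Of 13 clock genes 3 rose and 1 fell (median 0.10, and -0.75 with no scaling factor; camera adjusted p = 0.221). Of 15 cell division genes 5 rose and 1 fell (median 0.30, and -0.57 with no scaling factor; camera adjusted p = 0.254). Of 9 genes of organellar RNA polymerases and sigma factors 2 rose and 1 fell (median 0.05, and -0.82 with no scaling factor; camera adjusted p = 0.606). The clock gene PRR7 (AT5G02810) rose 3.67-fold and LHY (AT1G01060), a morning factor, fell 1.85-fold, while CYCD3;1 (AT4G34160), a cyclin of cell cycle entry, fell 1.74-fold. Root markers fell in 4 of 10 cases (median -0.74; camera adjusted p = 0.114). PYK10 (AT3G09260), a root glucosidase, stood at 258 ± 5.57 CPM against 453 ± 70.7. Seed maturation genes, markers of left-over seed, rose in 2 of 10 cases (median 0.12, and -0.72 with no scaling factor; camera adjusted p = 0.377, and adjusted p = 0.0165 with no scaling factor). The list counts above were the same adjusted over the list alone. Rising cell division genes numbered 3 without control replicate 2 or priming replicate 2. Falling cell division genes numbered 2 without control replicate 3 or priming replicate 3. Rising seed maturation genes numbered 1 without priming replicate 1. There were 1 rising and 8 falling clock genes, 0 rising and 8 falling cell division genes and 0 rising and 8 falling polymerase and sigma factor genes with no scaling factor. The counts were 0 rising and 9 falling root markers (median -1.62) and 0 rising and 1 falling seed maturation genes with no scaling factor. Calls numbered 5 rising and 2 falling cell division genes with upper-quartile factors.

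Outside the lists, the largest increase after priming by the naming rule was that of PDX1.2 (AT3G16050), a regulator of vitamin B6 synthesis, from 6.86 ± 0.786 to 1866 ± 149 CPM. HSP70T-2 (AT2G32120) rose 175-fold, the Hsp70 partner Fes1A (AT3G09350) 145-fold and EGY3 (AT1G17870) 125-fold. DIP2 (AT5G03210), the plastid chaperonin subunit Cpn60beta2 (AT3G13470), PPI2 (AT3G15340), the transcription factor NAC019 (AT1G52890), FBS1 (AT1G61340) and the splicing regulator SR45a (AT1G07350) rose 33.0-fold to 98.4-fold. The largest decreases were the beta-glucosidases BGLU21 (AT1G66270), from 150.0 ± 10.96 to 15.6 ± 3.02 CPM, BGLU34 (AT1G47600), 7.41-fold lower, and BGLU22 (AT1G66280), 5.52-fold lower. GLL22 (AT1G54000), OXS3 (AT5G56550), BRH1 (AT3G61460), the suberin enzyme GPAT5 (AT3G11430), the laccases LAC3 (AT2G30210) and LAC5 (AT2G40370) and the cutin enzyme CYP86A8 (AT2G45970) were 4.82-fold to 7.17-fold lower.

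On the plastid genome, genes of photosystems, cytochrome b6f, ATP synthase and RuBisCO rose in 24 of 30 cases after priming (median 0.84, but -0.05 with no scaling factor; camera adjusted p = 1.68e-06 and adjusted p = 0.640 with an estimated correlation). The photosystem II genes psbC (ATCG00280) and psbD (ATCG00270) rose 2.45-fold and 2.25-fold. The NDH complex rose in 9 of 12 (median 0.54, but -0.34 with no scaling factor and -0.18 with scaling within the organelle; camera adjusted p = 0.0157 and adjusted p = 0.714 with an estimated correlation and adjusted p = 0.880 with no scaling factor). In that list ndhJ (ATCG00420) gave 0.82 ± 0.17 with TMM and -0.07 with no scaling factor. Plastid gene expression and other genes rose in 23 of 32 (median 0.43, but -0.45 with no scaling factor and -0.30 with scaling within the organelle; camera adjusted p = 3.38e-04 and adjusted p = 0.714 with an estimated correlation and adjusted p = 0.880 with no scaling factor). Mitochondrial respiratory chain and ATP synthase genes rose in all 23 cases (median 0.97, but -0.16 with scaling within the organelle; camera adjusted p = 2.6e-09 and adjusted p = 0.498 with an estimated correlation). The ATP synthase gene atp4 (ATMG00640) rose by log2 1.12 ± 0.14. The other mitochondrial list rose in all 14 (median 1.05, but -0.08 with scaling within the organelle; camera adjusted p = 6.9e-07 and adjusted p = 0.424 with an estimated correlation). Its ribosomal protein gene rps12 (ATMG00980) rose by log2 1.28 ± 0.14. In all, 188 of 213 organellar loci rose, the largest being the open reading frames ATMG00620, ATMG00170 and ATMG00810 with log2 2.82 ± 0.13, 2.77 ± 0.10 and 2.17 ± 0.14. Scaled within the plastid, 18 loci rose and 35 fell, and within the mitochondrion 39 rose and 20 fell. With no scaling factor 5 plastid loci rose and 44 fell, and 52 mitochondrial loci rose. 26 photosystem-list genes rose when adjusted over the list alone, with the other counts the same. The numbers became 4 rising and 6 falling photosystem-list genes, 0 rising and 9 falling NDH genes and 0 rising and 24 falling plastid gene expression genes with no scaling factor. Calls came to 1 rising and 0 falling respiratory genes (median 0.09) and 2 rising and 0 falling genes of the other mitochondrial list (median 0.16) with no scaling factor. Scaling within the plastid gave 11 rising and 4 falling photosystem-list genes (median 0.11), 0 rising and 6 falling NDH genes (median -0.18) and 4 rising and 20 falling plastid gene expression genes (median -0.30). Scaling within the mitochondrion gave 0 rising and 14 falling respiratory genes (median -0.16) and 0 rising and 4 falling genes of the other mitochondrial list (median -0.08).

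Over all 23596 loci tested, 6616 were higher and 6458 lower in priming than in control (edgeR), 1553 and 2576 of them by at least 1 on the log2 scale. With no scaling factor the calls were 1018 higher and 16944 lower and the median log2 change of all loci shifted by -0.86. Changes here and in the comparisons that follow are relative to the median locus.

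The comparison of heat shock with control asked how unprimed seedlings responded to 43 °C, and it also spans 1 day of age. Small heat shock proteins rose in 15 of 16 cases with a median log2 change of 4.15 (camera adjusted p = 2.83e-13 and adjusted p = 0.0989 with an estimated correlation). AT1G59860 went from 3.53 ± 0.762 to 435 ± 61.8 CPM and HSP17.4 (AT3G46230) from 0.682 ± 0.0528 to 21.7 ± 2.90 CPM. HSP21 reached 3.76 ± 0.614 CPM (log2 3.56 ± 0.17, edgeR adjusted p = 6.53e-10). All 16 cytosolic and nuclear chaperones rose (median 2.19; camera adjusted p = 2.94e-10 and adjusted p = 0.271 with an estimated correlation). HSP101 reached 750.4 ± 106 CPM (log2 4.30 ± 0.17, edgeR adjusted p = 1.17e-10), BAG6 rose 30.7-fold and HOP3 (AT4G12400), a co-chaperone that links Hsp70 and Hsp90, 19.1-fold. 1 small heat shock protein fell when adjusted over the list alone, with the other counts the same. Falling small heat shock proteins numbered 1 without control replicate 3 or primed heat shock replicate 3. The counts became 15 rising and 1 falling small heat shock proteins (median 3.66) with no scaling factor.

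HSFA2 rose to 189 ± 23.0 CPM in heat shock (log2 7.07 ± 0.17, edgeR adjusted p = 8.61e-13). Of all 21 heat shock factors 10 rose and 4 fell (median 0.33, but -0.15 with no scaling factor; camera adjusted p = 0.0979). HSFA7A rose by 4.103 ± 0.15 and HSFB4 (AT1G46264) changed by -2.13 ± 0.20. Memory genes rose in 9 and fell in 3 of 12 cases (median 3.26; camera adjusted p = 1.58e-04 and adjusted p = 0.271 with an estimated correlation). The plastid protease FTSH6 (AT5G15250) rose 15.3-fold. Chaperones of mitochondria and plastids rose in 7 and fell in 2 of 15 cases (median 0.20, but -0.28 with no scaling factor; camera adjusted p = 0.0944). MTHSC70-2 rose 4.09-fold and CLPB3 2.03-fold. In the unfolded protein response 13 of 17 genes fell and 2 rose (median -0.51; camera adjusted p = 8.94e-04 and adjusted p = 0.416 with an estimated correlation and adjusted p = 0.0579 with no scaling factor). BIP2 fell 2.12-fold, to 57.3 ± 4.44 CPM, and the calreticulin CRT1 (AT1G56340) 2.09-fold, whereas BIP3 (AT1G09080), a stress-induced form, rose from 0.192 ± 0.109 to 7.88 ± 0.759 CPM and ATERDJ3A rose 3.00-fold. 5 heat shock factors fell when adjusted over the list alone, with the other counts the same. Falling organelle chaperones numbered 1 without heat shock replicate 2 or 3. There were 5 rising and 8 falling heat shock factors and 2 rising and 6 falling organelle chaperones with no scaling factor. The counts were 9 rising and 1 falling organelle chaperones with upper-quartile factors.

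Ribosomal proteins fell in 7 of 14 cases after heat shock (median -0.29; camera adjusted p = 0.00655 and adjusted p = 0.661 with an estimated correlation). RPL24B (AT3G53020) fell 1.72-fold. ONSEN copies rose in 6 of 8 (median 1.07; camera adjusted p = 0.00319 and adjusted p = 0.463 with an estimated correlation). AT1G58140 rose by log2 1.25 ± 0.18. Abscisic acid and dehydration genes rose in 3 and fell in 6 of 15 (median -0.48; camera adjusted p = 0.428). DREB2A rose 6.14-fold and GOLS1 5.06-fold while GOLS2 (AT1G56600) fell 3.24-fold. In the oxidative stress list 5 rose and 2 fell of 12 (median 0.07, but -0.42 with no scaling factor; camera adjusted p = 0.371). ZAT12 rose 2.67-fold. The mitochondrial dysfunction response rose in 5 of 15 (median 0.49; camera adjusted p = 0.393). SOT12 (AT2G03760), a sulfotransferase, rose 2.201-fold. Nuclear photosynthesis genes rose in 13 of 28 (median 0.32, but -0.17 with no scaling factor; camera adjusted p = 0.0554). PSBO2 rose by log2 0.57 ± 0.13, and without a call by 0.09 with no scaling factor. 8 ribosomal proteins fell and 3 mitochondrial dysfunction genes rose when adjusted over the list alone, with the other counts the same. Falling oxidative stress genes numbered 0 without control replicate 1 or heat shock replicate 2 or 3, and 1 without control replicate 3 or primed heat shock replicate 2 or 3. Rising mitochondrial dysfunction genes numbered 2 without heat shock replicate 1 or 2, and 3 without control replicate 2. Falling mitochondrial dysfunction genes numbered 1 without priming replicate 3 or primed heat shock replicate 3. Rising photosynthesis genes numbered 5 without heat shock replicate 2, and 6 without control replicate 2 or heat shock replicate 3. Falling photosynthesis genes numbered 1 without priming replicate 1. Calls numbered 0 rising and 14 falling ribosomal proteins (median -0.77), 3 rising and 10 falling dehydration genes (median -0.96) and 3 rising and 7 falling oxidative stress genes with no scaling factor. The numbers became 2 rising and 5 falling mitochondrial dysfunction genes (median 0.03) and 0 rising and 12 falling photosynthesis genes with no scaling factor. Calls came to 5 rising and 1 falling oxidative stress genes with RLE factors or upper-quartile factors.

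Clock genes rose in 3 and fell in 6 of 13 cases (median -0.37; camera adjusted p = 0.189). LHY fell 2.87-fold. Of 15 cell division genes 3 rose and 4 fell (median -0.27; camera adjusted p = 0.495). CYCD3;1 rose 2.39-fold and the replication factor MCM2 (AT1G44900) fell 2.55-fold. Of 9 organellar polymerase and sigma factor genes 2 rose and 1 fell (median -0.09, but 0.01 with upper-quartile factors; camera adjusted p = 0.903). SCA3 (AT2G24120), a plastid RNA polymerase, gave log2 0.78 ± 0.09, and without a call 0.29 with no scaling factor. Seed maturation genes fell in 4 and rose in 1 of 10 cases (median -1.07; camera adjusted p = 0.221). The oleosin OLE2 (AT5G40420) fell 2.12-fold. The rise was that of EM1 (AT3G51810), whose call ended with replicate as a block (edgeR adjusted p = 0.0738, in a range of 0.0341 to 0.658 over all alternatives). Root markers fell in 2 of 10 (median -0.39; camera adjusted p = 0.257). The call of the aquaporin TIP2;3 (AT5G47450) among them ended with the block (edgeR adjusted p = 0.0951, range 0.00463 to 0.218), as did that of COR15A (AT2G42540) in the dehydration list (edgeR adjusted p = 0.0735, range 0.00711 to 0.184). Among root markers the count of falls adjusted over the list alone was 0 with edgeR, where the unadjusted p was under 0.05 for 2 and DESeq2 called 1 over all loci. 7 clock genes fell when adjusted over the list alone, with the other counts the same. Rising clock genes numbered 1 without control replicate 1 or 3 or heat shock replicate 1. Falling cell division genes numbered 2 without heat shock replicate 3. Rising polymerase and sigma factor genes numbered 1 without control replicate 1 or 3 or heat shock replicate 1 or 2. Falling polymerase and sigma factor genes numbered 0 without control replicate 2 or heat shock replicate 2 or 3, and 2 without control replicate 3 or heat shock replicate 1. Rising seed maturation genes numbered 0 without control replicate 1 or 2, priming replicate 3 or any heat shock or primed heat shock library. Falling seed maturation genes numbered 1 without control replicate 3 or heat shock replicate 1 or 3, and 2 without heat shock replicate 2. Falling root markers numbered 0 without heat shock replicate 1 or 2, and 1 without control replicate 1, priming replicate 2, heat shock replicate 3 or primed heat shock replicate 2 or 3. The counts became 0 rising and 8 falling clock genes (median -0.83), 3 rising and 8 falling cell division genes (median -0.76) and 0 rising and 6 falling polymerase and sigma factor genes (median -0.57) with no scaling factor. There were 0 rising and 5 falling seed maturation genes (median -1.55) and 0 rising and 8 falling root markers (median -0.88) with no scaling factor. The counts were 3 rising and 0 falling polymerase and sigma factor genes with upper-quartile factors. Calls numbered 0 rising and 1 falling root markers with RLE factors or upper-quartile factors or DESeq2.

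Outside the lists the largest increases after heat shock were the cytochrome P450 CYP81G1 (AT5G67310), from 0.305 ± 0.101 to 21.4 ± 0.783 CPM, PDX1.2 at 27.9-fold and the inositol phosphatase 5PTase12 (AT2G43900) at 6.03-fold. PMT6 (AT4G36670), WRKY40 (AT1G80840), the ATP synthase subunit ATPC2 (AT1G15700), the deadenylases CAF1b (AT5G22250) and CAF1a (AT3G44260), the ethylene synthesis enzyme ACS7 (AT4G26200) and ABCG42 (AT4G15233) rose 3.99-fold to 5.38-fold. Decreases were led by MLP28 (AT1G70830), from 34.2 ± 28.9 to 2.99 ± 0.586 CPM. The arabinogalactan proteins FLA8 (AT2G45470) and AGP31 (AT1G28290), the glucanase GH9B13 (AT4G02290), ELP (AT1G12090) and PELPK1 (AT5G09530) were 3.86-fold to 5.65-fold lower. CAD9 (AT4G39330), LCR68 (AT2G02130), the myrosinase TGG1 (AT5G26000) and BGLU34 were 3.81-fold to 4.22-fold lower.

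Plastid genes of photosystems, cytochrome b6f, ATP synthase and RuBisCO rose in 13 and fell in 5 of 30 cases after heat shock (median 0.41, but -0.09 with no scaling factor; camera adjusted p = 0.298). psbA rose from 190122 ± 37683 to 429203 ± 73675 CPM and psbN (ATCG00700) rose 2.32-fold, whereas atpF (ATCG00130) fell 2.70-fold. Plastid gene expression and other genes fell in 23 of 32 and rose in 1 (median -0.64; camera adjusted p = 4.58e-05 and adjusted p = 0.688 with an estimated correlation). Among them ATCG00040, rpl14 (ATCG00780) and rpl16 (ATCG00790) were 2.04-fold to 2.22-fold lower. The NDH complex fell in 2 of 12 (median -0.09, but 0.01 with upper-quartile factors; camera adjusted p = 0.501, and adjusted p = 0.0441 with no scaling factor). Its subunit gene ndhF (ATCG01010) fell 1.85-fold. Mitochondrial respiratory genes rose in all 23 cases (median 0.58, but -0.13 with scaling within the organelle; camera adjusted p = 2.24e-05 and adjusted p = 0.640 with an estimated correlation). The oxidase gene cox1 (ATMG01360) rose by log2 0.79 ± 0.15. The other mitochondrial list rose in all 14 (median 0.57, but -0.13 with scaling within the organelle; camera adjusted p = 4.48e-04 and adjusted p = 0.640 with an estimated correlation). ATMG00180 rose by log2 0.80 ± 0.13. In all, 130 organellar loci rose and 35 fell of 213, the largest rise being ATMG00030 at 2.86-fold. Scaled within each organelle, 30 plastid loci rose and 44 fell, and 47 mitochondrial loci rose and 25 fell. With no scaling factor 4 plastid loci rose and 58 fell, and 50 mitochondrial loci rose. The list counts above were the same adjusted over the list alone. Rising photosystem-list genes numbered 7 without control replicate 3 or heat shock replicate 3. Rising plastid gene expression genes numbered 0 without heat shock replicate 2 or 3 or any control library, and 2 without priming replicate 1 or heat shock replicate 1. The numbers became 4 rising and 11 falling photosystem-list genes, 0 rising and 27 falling plastid gene expression genes (median -1.13) and 0 rising and 11 falling NDH genes (median -0.58) with no scaling factor. Calls came to 1 rising and 0 falling respiratory genes (median 0.08) and 2 rising and 0 falling genes of the other mitochondrial list (median 0.08) with no scaling factor. The counts became 3 rising and 19 falling plastid gene expression genes with upper-quartile factors. There were 2 rising and 22 falling plastid gene expression genes with DESeq2. Scaling within the plastid gave 19 rising and 7 falling photosystem-list genes (median 0.40), 1 rising and 6 falling NDH genes (median -0.09) and 5 rising and 25 falling plastid gene expression genes (median -0.64). Scaling within the mitochondrion gave 1 rising and 11 falling respiratory genes (median -0.13) and 2 rising and 5 falling genes of the other mitochondrial list (median -0.13).

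Over all loci 5965 were higher and 6291 lower in heat shock than in control (edgeR), 2887 and 1527 by at least 1 on the log2 scale. With upper-quartile factors the calls were 7146 higher and 4984 lower, and with no scaling factor 2768 higher and 13036 lower, with a shift of the median by -0.48. Age and heat cannot be told apart, because no unheated seedlings of 7 days were analysed here.

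The comparison of primed heat shock with heat shock asked what the earlier 38 °C treatment changed in seedlings of the same age at 43 °C. Small heat shock proteins were higher in 13 of 16 cases and lower in 1, with a median log2 difference of 3.13 (camera adjusted p = 1.11e-18 and adjusted p = 0.0646 with an estimated correlation). HSP21 stood at 821 ± 102 CPM against 3.76 ± 0.614 (log2 7.77 ± 0.18, edgeR adjusted p = 5.7e-13), HSP18.2 at 497 ± 22.9 against 4.09 ± 0.601 and ATHSP22.0 at 715 ± 75.8 against 10.4 ± 2.26 CPM. Memory genes were higher in 10 and lower in 1 of 12 cases (median 3.24; camera adjusted p = 3.87e-11 and adjusted p = 0.0646 with an estimated correlation). APX2 was higher by log2 7.30 ± 0.24 and HSA32 (AT4G21320), needed for lasting thermotolerance, by 2.86 ± 0.12. HSFA2 went the other way, from 189 ± 23.0 to 60.5 ± 11.4 CPM (log2 -1.65 ± 0.13, edgeR adjusted p = 4.56e-07). 14 small heat shock proteins were higher and 2 memory genes were lower when adjusted over the list alone, with the other counts the same. Lower small heat shock proteins numbered 0 without control replicate 1, priming replicate 2 or 3, heat shock replicate 2 or 3 or primed heat shock replicate 1 or 2. The counts were 14 higher and 0 lower small heat shock proteins (median 3.25) with no scaling factor.

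HSP101 stood at 1040.3 ± 190.4 CPM after primed heat shock and 750.4 ± 106 after heat shock (log2 0.47 ± 0.15, edgeR adjusted p = 0.0358). That call ended without heat shock replicate 1 (adjusted p = 0.122), heat shock replicate 3 (0.101), primed heat shock replicate 1 (0.0565) or primed heat shock replicate 3 (0.177), in a range of 2.22e-04 to 1 over all alternatives. Among cytosolic and nuclear chaperones 7 were higher and 5 lower of 16 (median 0.24; camera adjusted p = 0.382). Hsp70b was 7.80-fold higher and Hsp70-2 (AT5G02490) 3.74-fold lower. Chaperones of mitochondria and plastids were higher in 9 of 15 (median 0.80; camera adjusted p = 1.36e-06 and adjusted p = 0.0765 with an estimated correlation). The plastid Hsp70 CPHSC70-1 (AT4G24280) stood at 623 ± 28.4 against 134 ± 0.772 CPM and CLPB3 at 659 ± 44.8 against 174 ± 14.8. Of the heat shock factors 7 were higher and 4 lower (median -0.10, with 0.03 as the median with no scaling factor, and mean 0.20; camera adjusted p = 0.501 in the upward direction). HSFA1E (AT3G02990) was higher by log2 3.00 ± 0.17. In the unfolded protein response 2 were higher and 2 lower of 17 (median -0.04, with 0.07 as the median with no scaling factor, and mean 0.06; camera adjusted p = 0.733 in the downward direction). BIP1 was 2.23-fold higher. 8 cytosolic chaperones were higher and 6 cytosolic chaperones were lower when adjusted over the list alone, with the other counts the same. Lower heat shock factors numbered 2 without heat shock replicate 1 or primed heat shock replicate 1 or 2. Lower unfolded protein response genes numbered 0 without control replicate 1 or any heat shock or primed heat shock library, and 1 without control replicate 2 or priming replicate 2 or 3. Calls numbered 2 higher and 0 lower unfolded protein response genes with no scaling factor.

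**Figure D3:**
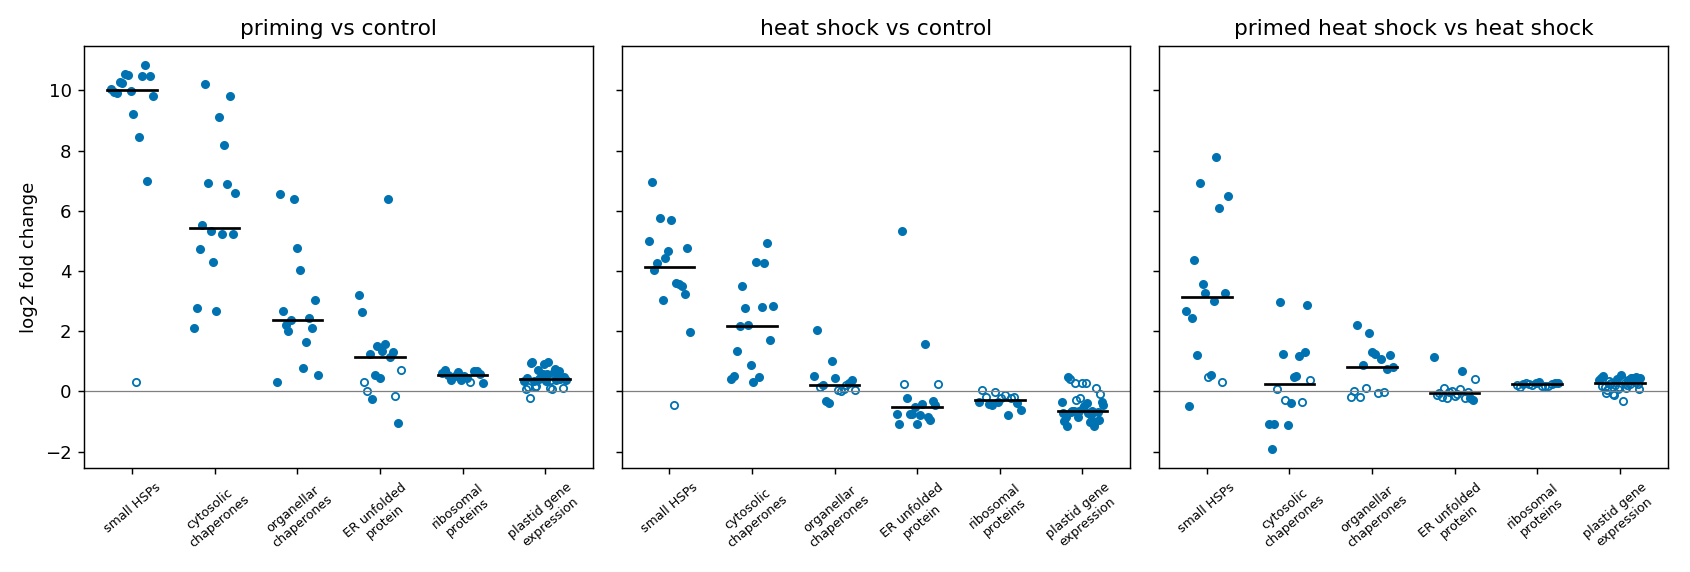
Log2 fold change of each measured member of 6 lists in priming vs control, heat shock vs control and primed heat shock vs heat shock. Filled points passed the test at an adjusted p under 0.05, open points did not, and the line is the list's median. The median of the small heat shock proteins is 10.02, 4.15 and 3.13 in turn, and that of the unfolded protein response 1.14, -0.51 and -0.04, the last being 0.07 with no scaling factor. Ribosomal proteins and plastid gene expression in priming lie at -0.33 and -0.45 with no scaling factor.

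Oxidative stress genes were higher in 5 of 12 cases after primed heat shock (median 0.38; camera adjusted p = 0.0220 and adjusted p = 0.564 with an estimated correlation). The cytosolic ascorbate peroxidase APX1 (AT1G07890) was 1.76-fold higher. ONSEN copies were higher in 7 of 8 (median 1.49; camera adjusted p = 5.97e-08 and adjusted p = 0.136 with an estimated correlation). AT1G48710 was higher by log2 2.91 ± 0.18. The organellar RNA polymerases and sigma factors were higher in 6 of 9 (median 0.46; camera adjusted p = 0.00203 and adjusted p = 0.271 with an estimated correlation). SCA3 stood at 54.0 ± 1.77 against 24.3 ± 1.29 CPM, and SIG6 (AT2G36990), a plastid sigma factor, was 1.48-fold higher. Ribosomal proteins were higher in 5 of 14 by at most 0.30 (median 0.25; camera adjusted p = 0.00174 and adjusted p = 0.640 with an estimated correlation). The calls of RPL23AA (AT2G39460) and RPS13A (AT4G00100) ended with replicate as a block (edgeR adjusted p = 0.0536 and 0.0525, in ranges of 0.0273 to 1.00 and 0.0144 to 1.00 over all alternatives). Dehydration genes were higher in 4 and lower in 2 of 15 (median 0.36; camera adjusted p = 0.189). GOLS1 stood at 1788 ± 153 against 129.6 ± 19.6 CPM and DREB2A was 1.71-fold lower. The mitochondrial dysfunction response was higher in 2 and lower in 4 of 15 (median -0.23; camera adjusted p = 0.242). The glutathione transferase GSTU24 (AT1G17170) was 2.13-fold lower. 6 oxidative stress genes were higher, 6 ribosomal proteins were higher, 5 dehydration genes were higher and 5 mitochondrial dysfunction genes were lower when adjusted over the list alone, with the other counts the same. Lower oxidative stress genes numbered 1 without primed heat shock replicate 3. Higher polymerase and sigma factor genes numbered 3 without heat shock replicate 2 or 3 or primed heat shock replicate 1 or 2. Higher ribosomal proteins numbered 0 without heat shock replicate 2 or 3 or primed heat shock replicate 1 or 2, 1 without priming replicate 2 or 3, 2 without primed heat shock replicate 3, and 3 without control replicate 1. Higher dehydration genes numbered 7 without control replicate 3. Lower mitochondrial dysfunction genes numbered 1 without primed heat shock replicate 2, and 2 without control replicate 2, priming replicate 2, heat shock replicate 1 or 2 or primed heat shock replicate 1 or 3. The numbers became 1 higher and 0 lower ribosomal proteins with RLE factors or upper-quartile factors. Calls came to 1 higher and 0 lower ribosomal proteins (median 0.36) and 4 higher and 1 lower dehydration genes (median 0.48) with no scaling factor. The counts became 3 higher and 0 lower ribosomal proteins with nuclear-only scaling.

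Clock genes were higher in 6 and lower in 1 of 13 cases (median 0.51; camera adjusted p = 0.134). CCA1 (AT2G46830), a morning factor, was 2.60-fold and LNK1 (AT5G64170) 1.77-fold higher. Nuclear photosynthesis genes were higher in 5 and lower in 1 of 28 (median -0.01, and 0.11 with no scaling factor; camera adjusted p = 0.779 in the upward direction). PSBO2 was 1.73-fold higher and the antenna gene LHCB1.4 (AT2G34430) 3.42-fold lower. Cell division genes were lower in 2 of 15 (median -0.02, but 0.10 with no scaling factor; camera adjusted p = 0.552). Root markers were lower in 3 and higher in 1 of 10 (median -0.51; camera adjusted p = 0.221, and adjusted p = 0.0441 with no scaling factor). COBL9 (AT5G49270), of root hairs, was 2.23-fold lower and PYK10 1.45-fold higher. The call of the nitrate transporter NRT2.1 (AT1G08090) ended with replicate as a block (edgeR adjusted p = 0.0519, range 0.00128 to 0.638 over all alternatives). Seed maturation genes had 0 calls of 10 by edgeR and 0 by DESeq2, with 0 at an unadjusted p under 0.05 (median 0.13; camera adjusted p = 0.495). 2 clock genes were lower and 4 root markers were lower when adjusted over the list alone, with the other counts the same. Higher clock genes numbered 2 without heat shock replicate 2 or 3 or primed heat shock replicate 2. Lower clock genes numbered 0 without heat shock replicate 1 or 3 or primed heat shock replicate 1 or 2, and 2 without priming replicate 1 or 3. Higher photosynthesis genes numbered 1 without primed heat shock replicate 1, 2 without heat shock replicate 3, and 3 without heat shock replicate 2. Lower photosynthesis genes numbered 2 without control replicate 3, priming replicate 1 or heat shock replicate 1. Lower cell division genes numbered 0 without primed heat shock replicate 1, and 1 without heat shock replicate 1 or 2 or primed heat shock replicate 3. Lower root markers numbered 1 without heat shock replicate 3 or primed heat shock replicate 2. There were 6 higher and 2 lower clock genes and 5 higher and 2 lower photosynthesis genes with upper-quartile factors or DESeq2. The counts were 4 higher and 0 lower clock genes (median 0.62), 6 higher and 2 lower photosynthesis genes and 0 higher and 1 lower cell division genes with no scaling factor.

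Outside the lists, genes higher in primed heat shock were led by ABCF2 (AT5G09930), from 1.079 ± 0.0963 to 20.4 ± 3.25 CPM, the alpha-galactosidase AGAL1 (AT5G08380) at 12.9-fold and the synaptotagmin SYTD (AT5G11100) at 10.09-fold. HSP70T-2, the anthocyanin enzyme LDOX (AT4G22880), EGY3, the plastid RNA-binding protein HCF152 (AT3G09650), ELIP1 (AT3G22840), a light stress protein, UGP2 (AT5G17310) and PTAC17 (AT1G80480) were 5.38-fold to 8.80-fold higher. Among lower genes were the flagellin receptor FLS2 (AT5G46330), from 43.0 ± 12.6 to 10.4 ± 2.58 CPM, the defence genes WRKY53 (AT4G23810), FRK1 (AT2G19190) and PBS3 (AT5G13320), 3.18-fold to 3.36-fold lower, and the potassium transporter HAK5 (AT4G13420), 3.27-fold lower. KCS12 (AT2G28630), IGMT4 (AT1G21130), XBAT34 (AT4G14365), BGLU22 and the glutathione transferase GSTF7 (AT1G02920) were 3.24-fold to 3.92-fold lower. The call of GSTF7 ended without primed heat shock replicate 1 (edgeR adjusted p = 0.0509, in a range of 1.83e-06 to 0.554 over all alternatives).

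Plastid gene expression and other plastid genes were higher in 11 of 32 cases after primed heat shock (median 0.27; camera adjusted p = 0.00147 and adjusted p = 0.753 with an estimated correlation). The RNA polymerase subunit gene rpoC2 (ATCG00170) was higher by log2 0.53 ± 0.12. Genes of photosystems, cytochrome b6f, ATP synthase and RuBisCO were lower as a list (median -0.18; camera adjusted p = 0.0181 and adjusted p = 0.784 with an estimated correlation) with 1 call of 30. This was psbN, at 348 ± 53.9 against 748 ± 103 CPM. The NDH complex was higher in 2 of 12 (median -0.16; camera adjusted p = 0.549). These were the copies ATCG00890 and ATCG01250 of ndhB in the inverted repeat, which share reads. Mitochondrial respiratory genes were lower in 1 of 23 cases (median -0.13; camera adjusted p = 0.0979). This was nad6 (ATMG00270), with a log2 difference of -0.39 ± 0.12. In the other mitochondrial list 3 were higher and 1 lower of 14 (median -0.06, but 0.06 with no scaling factor; camera adjusted p = 0.884). The gene ccmC (ATMG00900) of cytochrome c maturation was 2.49-fold lower. 13 plastid gene expression genes were higher when adjusted over the list alone, with the other counts the same. The exception was nad6, past the threshold over all loci (edgeR adjusted p = 0.0260, in a range of 0.00756 to 1.00 over all alternatives) and not over its list alone. Higher plastid gene expression genes numbered 3 without heat shock replicate 1 or primed heat shock replicate 3, 4 without primed heat shock replicate 1, and 7 without heat shock replicate 2 or 3. Lower photosystem-list genes numbered 2 without control replicate 3, priming replicate 2 or 3 or heat shock replicate 1, and 3 without priming replicate 1. Lower NDH genes numbered 1 without priming replicate 1 or 2, and 2 without primed heat shock replicate 3. Lower respiratory genes numbered 0 without heat shock replicate 2 or 3 or primed heat shock replicate 1 or 2. Higher genes of the other mitochondrial list numbered 1 without heat shock replicate 1 or 2 or primed heat shock replicate 1 or 3. Lower genes of the other mitochondrial list numbered 2 without primed heat shock replicate 3. Calls numbered 17 higher and 0 lower plastid gene expression genes (median 0.40), 0 higher and 3 lower photosystem-list genes (median -0.06) and 1 higher and 0 lower respiratory genes (median -0.02) with no scaling factor. The numbers became 0 higher and 3 lower photosystem-list genes and 2 higher and 1 lower NDH genes with DESeq2. In all, 37 organellar loci were higher and 3 lower of 213. The sum of both fell to 13, 20 and 21 without heat shock replicate 1, 2 or 3, and to 12 and 17 without primed heat shock replicate 1 or 3. Scaled within each organelle, 36 plastid loci were higher and 13 lower, and 40 mitochondrial loci were higher and 28 lower. With no scaling factor 24 plastid loci were higher and 3 lower, and 32 mitochondrial loci were higher and 2 lower. Scaling within the plastid gave 0 higher and 8 lower photosystem-list genes (median -0.07), 3 higher and 4 lower NDH genes (median -0.06) and 24 higher and 1 lower plastid gene expression genes (median 0.39). Scaling within the mitochondrion gave 1 higher and 18 lower respiratory genes (median -0.24) and 2 higher and 7 lower genes of the other mitochondrial list (median -0.16).

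Over all loci 3020 were higher and 2735 lower in primed heat shock than in heat shock (edgeR), 682 and 754 by at least 1 on the log2 scale. With no scaling factor the calls were 2790 higher and 1408 lower, with a shift of the median by 0.12. Seedlings that recovered from 38 °C without a later heat shock were not analysed here. A level in primed heat shock thus holds what the first treatment left and the second added.

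Primed heat shock against control spans both treatments and 1 day of age. Small heat shock proteins were higher in 15 of 16 cases (median 7.81), HSP21 by 11.34 ± 0.21, and memory genes in 11 of 12 (median 5.10). HSP101 was higher by 4.77 ± 0.18 and HSFA2 by 5.43 ± 0.16 on the log2 scale. Cytosolic and nuclear chaperones were higher in 11 and lower in 2 of 16 (median 2.73), and the unfolded protein response was lower in 11 and higher in 3 of 17 (median -0.56). The list counts above were the same adjusted over the list alone. Calls came to 11 higher and 4 lower cytosolic chaperones (median 2.36) with no scaling factor. Over all loci 7031 were higher and 7005 lower (edgeR), 3254 and 2401 by at least 1 on the log2 scale. With no scaling factor the calls were 3695 higher and 10752 lower, with a shift of the median by -0.36.

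Heat shock against priming sets 43 °C at 7 days beside 38 °C at 6 days, each for 30 min. Of the 54 listed chaperone and memory genes, 53 were lower after 43 °C, with a median of -3.46. HSP101 differed by -4.81 ± 0.18, HSFA2 by -3.08 ± 0.14 and HSP21 by -6.92 ± 0.17 on the log2 scale. All 16 small heat shock proteins were lower (median -5.53; camera adjusted p = 2.25e-14 and adjusted p = 0.0648 with an estimated correlation). The chaperones of mitochondria and plastids were lower in 14 of 15 (median -2.31; camera adjusted p = 9.35e-11, and still adjusted p = 0.0327 with an estimated correlation). Root markers were higher in 3 of 10 (median 0.17; camera adjusted p = 0.576). None of the list counts above changed when adjusted over the list alone. Lower root markers numbered 1 without control replicate 3. The counts became 1 higher and 13 lower organelle chaperones with upper-quartile factors. There were 1 higher and 13 lower organelle chaperones (median -1.92) and 5 higher and 0 lower root markers (median 0.54) with no scaling factor. Over all loci 7311 were higher and 7397 lower (edgeR), 3811 and 1967 by at least 1 on the log2 scale. The calls were 8749 higher and 5846 lower with upper-quartile factors, which shift the median by 0.14, and 10307 higher and 2729 lower with no scaling factor, with a shift by 0.38.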

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

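Tests of heat genes between 43 °C and 38 °C and of other splits were chosen only after the result was seen. So was that of both read classes left out together. The remaining tests of totals and of left-over transcripts were chosen before.

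Unfolded protein response genes had medians of opposite sign against control, 1.14 at 38 °C with 11 of 17 genes rising and 2 falling, and -0.51 at 43 °C with 2 rising and 13 falling. Heat shock against priming was itself tested. The list had a median log2 difference of -1.51 (camera adjusted p = 2.84e-06 and adjusted p = 0.173 with an estimated correlation), cytosolic ribosomal proteins of -0.82 (camera adjusted p = 1.09e-06 and adjusted p = 0.312 with an estimated correlation) and plastid gene expression of -0.86 (camera adjusted p = 3.51e-09 and adjusted p = 0.427 with an estimated correlation). The medians with no scaling factor were -1.13, -0.44 and -0.48, and with TMM ribosomal proteins lay -0.58 from nuclear loci of the same level. In priming against control the latter pair turned from 0.54 and 0.43 to -0.33 and -0.45 with no scaling factor. Single genes with opposite responses, chosen after their values were seen, were the chaperone BIP2, with a log2 difference of -3.74 between heat shock and priming, and the galactinol synthase GOLS2, with -3.52. Unaligned reads were 2.33 percentage points more frequent in priming than in control. In heat shock they were 4.99 points more frequent (16.5% ± 1.36 against 11.5% ± 0.258). Both exact permutation tests gave p = 0.1, the smallest possible. A separate reference entry for the ONSEN retrotransposon, outside the gene loci, held 0.616 ± 0.116 CPM without scaling factors in primed heat shock and 0.927 ± 0.0507 in heat shock, against 0.0472 ± 0.0146 in control and 0.0654 ± 0.0205 in priming (log2 4.75 ± 0.36 for heat shock against control, edgeR adjusted p = 7.08e-08). Its edgeR difference in priming was 1.36 ± 0.46 (adjusted p = 0.0206), from 3 to 10 reads per priming library against 4 to 8 per control, and with no scaling factor it was 0.51 (adjusted p = 0.354), so the call rests on the scaling. In primed heat shock against heat shock it was -0.71 ± 0.28 (edgeR adjusted p = 0.0788). There 7 of 8 ONSEN copies among the gene loci were higher instead. In heat shock against priming the entry gave 3.39 ± 0.35 (edgeR adjusted p = 9.74e-07), and the copies a median of -0.41.

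Without scaling, the median nuclear locus was lower in priming than in control by a log2 difference of -0.79 (SD between libraries 0.169). Reads taken by the 54 listed chaperone and memory genes were not the whole cause, since the median was -0.63 (SD between libraries 0.187) with them out of the totals, and neither were organellar reads, with -0.70 (SD between libraries 0.0980). Loss of low-count loci is argued against by -0.66 (SD between libraries 0.140) among loci of at least 20 CPM. With both read classes left out the median was -0.36 (SD between libraries 0.107), so they may account for part of the shift and not all of it. Reads taken by other strongly induced genes, and a change in the total RNA of the nucleus per seedling, stay open and were not tested.

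Of the 54 listed chaperone and memory genes 53 were higher after 38 °C than after 43 °C and 49 to 53 over the scalings tried, with a median log2 difference of -3.46 for heat shock against priming. Dilution of nuclear reads by plastid reads as the whole cause is argued against by unscaled medians of -3.07 (SD between libraries 0.108) over all reads and -2.78 (SD between libraries 0.126) with organellar reads out of the totals, and the choice of scaling by a highest median of -3.09 over the scalings tried. Temperature and 1 day of age are confounded here and stay open.

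Differences between primed and unprimed heat shock may hold transcripts left from the pre-treatment. Of the 3020 loci higher in primed heat shock, 1606 had risen in priming, against 847 for independent lists, with no library shared. The odds ratio was 3.53 (Fisher's exact test p = 8.34e-216, loci not being independent). Left-over transcripts and a stronger new response predict the same, so they cannot be told apart. By the labels, priming was shorter than the pre-treatment. With no scaling factor 1018 loci rose in priming. Of the loci lower in primed heat shock 488, or 17.84%, had risen in priming, against 767 for independent lists (odds ratio 0.522). The bar of 5% set for this share beforehand lay below the 28.0% of independent lists, so it decides nothing and the cause of the decreases stays open.

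Of the 10 splits of each comparison's 6 libraries into 3 and 3, only the real one reached its count of changed loci. With 10 splits no share under 0.05 is possible. The real counts were 13074 for priming against control, 12256 for heat shock against control, 5755 for primed heat shock against heat shock, 14036 for primed heat shock against control and 14708 for heat shock against priming. The highest of the other splits was 2 for primed heat shock against heat shock and 0 for the others with edgeR, with 1550, 1097, 2101, 716 and 1184 loci at an unadjusted p under 0.05 in the same order. The 3 other splits that also part every pair of a harvest date had 0 at most. Other splits mix both groups, whose difference then widens the spread, so their low counts decide nothing.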

How the results depend on the processing

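The alternative chosen only after the data were seen adds nuclear loci matching the mitochondrial genome to the mitochondrial share. Counts of changed loci stayed within 1.5-fold of the main count under every alternative but glmTreat, which tests against a log2 change of 1. It gave 1906, 2424, 315, 3395 and 3423 in the order of the real counts above, fewer by its construction. Leaving out 1 library gave 11805 to 13066, 10308 to 13169, 3904 to 6560, 12520 to 14890 and 13386 to 15088, and replicate as a block 13201, 12486, 6057, 14226 and 14830. The block ended the 6 calls said above to end with it, and changed no other call of a named gene or list. For shares the block returns the same difference by construction, so it could not test them. Organellar loci changed in priming against control numbered 101 with no scaling factor and 112 with scaling within the organelle, and in primed heat shock against heat shock 61 and 117, and the cause was not tested. With 1 library left out they numbered 174 to 193, 146 to 169 and 12 to 53 in the main comparisons. With an estimated correlation 1, 0 and 0 lists passed camera, with 4, 1 and 4 at an unadjusted p under 0.05 and 19, 13 and 11 by fry.

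Without psbA the plastid share differed by 2.37, 4.13 and -2.17 percentage points in the main comparisons. With 1 library left out it differed by 3.29 to 7.09, 13.3 to 17.3 and -7.40 to -3.59 points. The mitochondrial share then differed by 0.140 to 0.228, 0.159 to 0.205 and 0.0106 to 0.108. The matching nuclear loci held 1.14% of counts in control and 1.29%, 1.26% and 1.37% in priming, heat shock and primed heat shock. With them added the mitochondrial share differed by 0.331, 0.301 and 0.167 points. In heat shock against control it differed by 0.281 with ribosomal RNA kept and 0.134 without its most abundant gene, and in primed heat shock against heat shock by -0.193 with ribosomal RNA kept, and the cause was not tested.

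Named genes were mostly picked for large changes past the threshold, which favours keeping the call in refits of these libraries. For 297 results on named genes, 6646 of 7121 alternative values kept direction and call and 459 the direction only. Another 16 changed sign, all with no scaling factor. They were, in priming against control, PCNA1 at -0.13, SIG2 at -0.51, RPS18A at -0.19, RPL3A at -0.21, AT2G19730 at -0.19, SCA3 at -0.52, EM6 at -0.022, LNK2 at -0.10, CYCB1;1 at -0.21, RPS6B at -0.16, ndhJ at -0.066, ndhK at -0.20, ndhC at -0.22 and ATCG01250 at -0.30, and in heat shock against control CLPB4 at -0.015 and AT5G15700 at -0.10, which follow from the shift of the median of all loci. Depth limits loci near the filter's minimum, and the alignment limits copies that share reads.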

Other observations

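Sequences outside the gene loci (noncoding RNAs, transposon or intergenic entries and microRNA precursors) were tested in the same fit. The entries named here were chosen after their values were seen. Of 2563 such entries, 374 were higher and 621 lower in priming than in control, and 1343 higher and 107 lower in heat shock. In primed heat shock against heat shock 141 were higher and 71 lower (all edgeR, adjusted over all sequences). Nuclear loci under 1 CPM had medians in the same directions, -0.254 in priming and 0.318 in heat shock. Level and scaling were not tested for these counts. The transposon entry Chr5_AT5TE95125 rose in priming by log2 12.17 ± 0.42, from a mean of 0.0143 to 67.5 CPM (n = 3), and stood at 1.42 CPM in heat shock and 5.53 CPM in primed heat shock. Chr4_AT4TE74230 rose by log2 3.72 ± 0.12, from 11.7 to 154 CPM. The noncoding RNA At5NC012410 showed log2 3.36 ± 0.19 in heat shock against control, with 3.72 CPM in control, 3.04 in priming, 38.1 in heat shock and 35.9 in primed heat shock. Chr5_AT5TE58950 was lower in primed heat shock than in heat shock, with log2 -1.29 ± 0.11, and the microRNA precursor ath-MIR5642b was higher, with log2 0.63 ± 0.16, at 201 against 130.1 CPM. Transposon entries can overlap genes and share reads, so single entries are uncertain.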
